A study of Mus musculus with 6 samples.

How the data were processed

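RNA from the whole cerebellum of 6 male mice at postnatal day 60 was extracted with TRIZOL and made into libraries by a sequencing company with its own protocol, per the labels' protocols. Whether the libraries keep the strand of the RNA, the read length and the counting program are not given in the sources used here. HISAT2, DESeq2 and the mouse genome build GRCm38.p6 are named in the submitters' processing notes, without versions. A single table was deposited, with 55098 genes, of which 54532 have an Ensembl identifier and 566 are loci without one. The deposited count columns hold whole-number counts per gene for each library, not normalized. The deposited FPKM columns hold the same counts divided by gene length and a library total that can be worked out from the values. The listed counts made up 93.8% to 97.7% of these totals, and what makes up the rest is not given in the sources used here. The share was lower in every KO library (94.5% ± 0.620 in KO and 96.6% ± 0.940 in WT, SD, n = 3 each; exact permutation p = 0.1). The authors' group means are a signal per group, and the KO means equal the counts divided by DESeq2 size factors (largest relative difference 4.97e-10 among means above 10). The deposited log2 fold changes and p-values are the authors' comparison of KO with WT. Of the genes listed, 23052 had no count in any library, and 2354 had counts and no value in the authors' comparison.

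Group and animal number were taken from the sample titles. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM normalization (factors 0.990 to 1.01), the filterByExpr filter by group (which left 17142 genes) and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Log2 fold changes are KO minus WT, the standard error is the absolute log2 fold change over the root of F, and CPM values are TMM-normalized. The fitted fold change of a gene with few or no counts in a group depends on the prior count. With 3 libraries per group, 1 count was worth 0.0633 to 0.0724 CPM, and counting intervals and floors cover counting error only. Chi-square values of pairs of libraries were 5.37 to 22.8 per degree of freedom, so that no library was a second copy of another.

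The 31 gene lists, the rule for named genes, the tests and the alternatives, other than those said to be added, were fixed before the data were examined, and 897 of 900 list entries were found in the table. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry on voom values were run as alternatives. Camera compares a list with the other genes, and fry tests whether its members move, on balance, one way. List scores are the mean log2 CPM (prior count 2) of the members, each centred over the 6 libraries. Named genes were Slc39a14 and the protein-coding called genes with a mean of at least 1 CPM and groups that do not overlap (up to 10 per direction by fold change and 5 by p). Since fewer than 10 passed, the 10 protein-coding genes of at least 1 CPM with the smallest p that did not pass were added. Then came up to 4 called members of each list, or else the 2 with the highest CPM, and 12 genes of metal transport and cell identity given in any case. Genes named outside this rule are said to be so or follow from a count of 5 or fewer. Alternatives covered other normalizations, filters, DESeq2 1.42.0, limma-voom, robust shrinkage, a fold threshold of 1.2, protein-coding genes, windows of 5 and 20 Mb and each library left out in turn. Tables were handled in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.

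The steps were tested on simulated data for KO against WT. Counts were drawn for 17142 genes from the observed means, library totals and trend of dispersion over gene level, with 200 genes changed. The edgeR test recovered 42% of the genes changed 1.5-fold, 60% at 2-fold, 94% at 4-fold and 98% at 8-fold, with 9 false calls among 156. Variation of single genes or libraries beyond that trend was not simulated. With 156 calls the unadjusted p needed for a call is also larger than with the few calls in the real data. These shares may thus be too high for the real libraries. A list raised 1.5-fold was called by camera, and 0 of 23 lists sharing no gene with it were. Genes were simulated independently of one another, so the 0 of 23 does not show how often camera calls unchanged lists whose genes vary together.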

Results

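RNA-seq was used to compare gene expression in the whole cerebellum of wild-type (WT) male mice and of male mice labelled as lacking Slc39a14 (KO) at postnatal day 60. Slc39a14 encodes ZIP14, a transporter of manganese, zinc and iron, and the series describes the KO mouse as a model of a childhood-onset dystonia with parkinsonism caused by manganese. The table held 3 libraries labelled WT, from animals 1, 3 and 5, and 3 labelled KO, from animals 2, 4 and 6, each animal giving 1 library. Total gene counts were 13851368, 15788135 and 13805997 in WT 1, 3 and 5. They were 15754275, 14297191 and 13912821 in KO 2, 4 and 6. No difference in totals was found in an exact two-sided permutation test (p = 0.6). The share of counts in the 10 most abundant genes was 4.41% ± 0.705 in KO and 4.25% ± 0.382 in WT (SD, n = 3 each; exact permutation p = 0.8). The smallest p that 3 against 3 animals allow in this test is 0.1. On the first principal component (29.6% of the variance of 1000 genes) WT 5 and KO 4 lay apart from the other 4 libraries, and the second (26.9%) separated the libraries labelled KO from those labelled WT. On the third (17.4%) WT 1 and KO 2 (-14.6 and -13.7) lay opposite WT 3 and KO 6 (13.7 and 13.6), with WT 5 and KO 4 between.

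The knocked-out gene was examined first. Slc39a14 (ENSMUSG00000022094, chromosome 14, 70303469 to 70351425, GRCm38.p6) had 582, 646 and 598 counts in WT 1, 3 and 5 and 654, 572 and 640 counts in KO 2, 4 and 6. In CPM, the TMM-normalized count scaled to library size, its level was 42.3 ± 3.18 in the libraries labelled KO and 42.4 ± 1.33 CPM in those labelled WT (SD, n = 3 each). The log2 fold change was -0.003 (SE 0.11, 95% interval -0.24 to 0.23, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.0). The transcript was therefore not lower in the libraries labelled KO, and the gene count did not check the genotype labels. Which part of the gene the allele lacks is not given in the sources used here. A count over the whole gene does not show the loss of a part that gives few of its reads. KO and WT below stand for the libraries labelled so, and every direction rests on these labels.

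Genes of the interferon response rose in the KO cerebellum. Among 17142 genes tested, 8 passed, all of them higher in KO, and 6 of the 8 belonged to the list of interferon response genes fixed before the data were examined. Oasl2, an antiviral protein of the oligoadenylate synthetase family, was at 16.6 ± 4.35 CPM in KO and 2.14 ± 0.592 CPM in WT (SD, n = 3 each; log2 fold change 2.96, SE 0.27, edgeR adjusted p = 0.0124). Ifit1, an inhibitor of viral RNA translation, rose from 2.48 ± 0.604 to 15.1 ± 4.25 CPM (log2 fold change 2.60, SE 0.27, edgeR adjusted p = 0.0126). Usp18, which removes the ubiquitin-like modifier ISG15 from proteins, rose from 0.732 ± 0.222 to 5.10 ± 1.17 CPM (log2 fold change 2.77, SE 0.33, edgeR adjusted p = 0.0237; n = 3 each). Ifi27, Ifit3 and Ifi27l2a rose with log2 fold changes of 1.60, 1.71 and 4.20 (SE 0.16, 0.20 and 0.56; edgeR adjusted p = 0.0126, 0.0237 and 0.0456).

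The other called genes were Lgals3bp, a secreted glycoprotein that binds galectin-3, and Cxcl13, a chemokine that attracts B cells. Lgals3bp rose from 7.72 ± 1.14 to 26.2 ± 5.05 CPM (SD, n = 3 each; log2 fold change 1.76, SE 0.18, edgeR adjusted p = 0.0126). Cxcl13 (edgeR adjusted p = 0.0271) had 33, 58 and 24 counts in KO 2, 4 and 6 and 1 count in all WT libraries together, a ratio of 114 with an exact 95% counting interval of 19.99 to 4527. In GRCm38.p6 Oasl2 lay on chromosome 5 (114896936 to 114912234), as did Cxcl13 (95956951 to 95961068). Usp18 lay on chromosome 6 (121245906 to 121270917) and Lgals3bp on chromosome 11 (118392751 to 118402092). Ifi27 (103434211 to 103440239) and Ifi27l2a (103442167 to 103443680) were neighbours on chromosome 12. Ifit1 (34640871 to 34650009) and Ifit3 (34583531 to 34588731) lay on chromosome 19. In each of these genes every KO library lay above every WT library. Chance separates 3 from 3 libraries, in either direction, for 10% of genes, and 7.26% of all tested genes were so separated. The called genes were picked for a small p, so their separation adds no support. Ifit3 has a near-identical copy, Ifit3b, and its count is uncertain to the extent that reads were split between them.

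**Figure D1:**
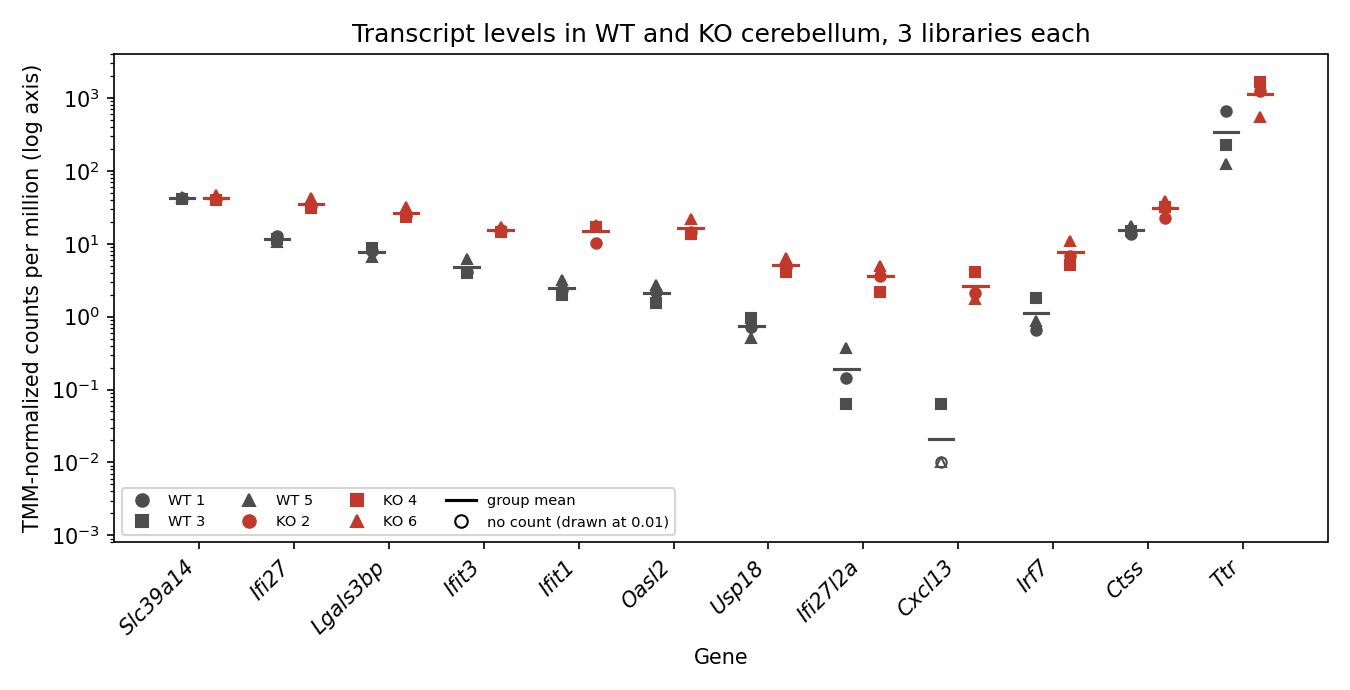
CPM (log axis) of 12 genes in each WT library (grey) and KO library (red), with horizontal lines at the group means of 3 libraries. Slc39a14 lies at 42.4 CPM in WT and 42.3 CPM in KO, the called genes Oasl2, Ifit1 and Usp18 lie higher in every KO than in every WT library, and Ttr varies widely within both groups.

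Of the 29 tested interferon response genes, 29 had a positive log2 fold change with a median of 1.47. Over all genes tested 6 of them rose, and adjusted over the list alone 27 rose. The list was called by camera (adjusted p = 2.36e-154 with a preset correlation of 0.01), with adjusted p = 0.0152 with an estimated correlation and adjusted p = 0.0275 with fry. Members that did not pass over all genes included Irf7, the transcription factor that amplifies interferon production (log2 fold change 2.75, SE 0.41, edgeR adjusted p = 0.0791). Ifi44, the RNA sensor Ddx58 and Rtp4 were at 2.89, 1.36 and 2.17 on the log2 scale (edgeR adjusted p = 0.0677, 0.0791 and 0.0791). Genes outside the list that did not pass included the antiviral genes Ddx60 (3.09), Zc3hav1 (1.41), Rnf213 (1.23) and Eif2ak2 (0.93), these 4 with edgeR adjusted p between 0.0872 and 0.154. Xlr4a, an X-linked gene of a family of close copies (X, 73074345 to 73082478), had 63, 23 and 15 counts in KO and 0 in all WT libraries, at least 33.3-fold higher against a floor of 3 counts over the WT group (edgeR adjusted p = 0.134). The number of genes called rested on single libraries: it was 0 without WT 1, 0 without WT 3, 28 without WT 5, 2 without KO 2, 14 higher and 3 lower without KO 4, and 3 without KO 6.

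No gene was called lower in KO by edgeR, with 182 genes lower and 289 higher at an unadjusted p under 0.05. These 471 of 17142 tested genes are fewer than the share of 0.05 that unchanged genes give. The number was 1029 with a term for WT 5 and KO 4, added to the fit after the data were seen. The count of lower genes was 0 by limma-voom on the same genes and 3 by DESeq2. DESeq2 was run without the low-count filter (32040 genes with a p-value), so the test and the filter changed together. DESeq2 called 38 genes, 35 of them higher, and these were the 38 genes called in the authors' deposited table. The lower genes in the authors' deposited table were Gm42372, Gm26782 and an unannotated locus on chromosome 17 (13166694 to 13185131), with log2 fold changes of -0.80, -0.73 and -1.24. All 38 had the same sign and an unadjusted p under 0.05 in the edgeR fit, which called 8 of them. Gm26782 is annotated as antisense and overlaps Tep1, and because the strand setting of the counting is not given in the sources used here its count is uncertain. Irf7, Rtp4 and Cxcl10 overlap Phrf1, Masp1 and Art3 on the opposite strand, and their counts are uncertain in the same way.

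The lists of microglia markers, activated microglia and reactive astrocytes were higher in KO by the preset correlation alone. Of 29 microglia markers 25 were positive (median 0.43) and 1 rose adjusted over the list alone. This was Ctss, a lysosomal protease (15.3 ± 2.02 CPM in WT and 30.8 ± 7.91 CPM in KO, SD, n = 3 each; log2 fold change 1.01, SE 0.20, edgeR adjusted p = 0.276 over all genes). Aif1, the microglial protein IBA1, was at 0.572 CPM in WT and 0.912 CPM in KO (log2 fold change 0.68, SE 0.52), and Fcrls was at -0.79 and did not pass. The microglia list had a camera adjusted p of 1.26e-11, and adjusted p = 0.174 with an estimated correlation. Its score per library was higher in each KO than in each WT library (difference 0.35 on the log2 scale, exact permutation p = 0.1, Benjamini-Hochberg 0.775 over 31 lists). The interferon score had the same permutation p, which is the smallest that 3 against 3 libraries allow, and the same adjusted value. Of 25 activated microglia and inflammation genes 20 were positive (median 0.24) and none passed. Their camera adjusted p was 2.97e-08, with adjusted p = 0.0597 with an estimated correlation, and their score in WT 5 (0.196) lay above KO 2 (-0.015; exact permutation p = 0.2). Apoe and Ctsb were at 0.13 and 0.07 on the log2 scale.

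Of 29 reactive astrocyte genes 23 were positive (median 0.18), and 1 rose adjusted over the list alone. This was the interferon-inducible chemokine Cxcl10 (0.339 ± 0.469 CPM in WT and 3.77 ± 0.617 CPM in KO; log2 fold change 3.48, SE 0.65, edgeR adjusted p = 0.229 over all genes). Gfap, the intermediate filament of astrocytes, was at 149 ± 11.9 CPM in WT and 162 ± 41.4 CPM in KO (log2 fold change 0.12, SE 0.16). The camera adjusted p of this list was 8.79e-06, with adjusted p = 0.197 with an estimated correlation, and here too the score of WT 5 (0.114) lay above KO 2 (0.051; exact permutation p = 0.2). The 26 astrocyte and Bergmann glia markers were not called (median 0.03, camera adjusted p = 0.518). The glutamate transporter Slc1a3 was at -0.03 on the log2 scale.

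Markers of the choroid plexus, a tissue that borders the cerebellum, varied widely between libraries. All 19 tested members were positive, with a median of 1.31. With single libraries left out the median ranged from 0.81 (without KO 4) to 1.93 (without WT 1), and it was 0.50 with WT 5 and KO 4 both left out. Of the 19 members, 0 rose over all genes and 16 rose adjusted over the list alone. Ttr, the transthyretin gene, was at 667, 229 and 123 CPM in WT 1, 3 and 5 and at 1236, 1655 and 554 CPM in KO 2, 4 and 6. KO 6 thus lay below WT 1 (log2 fold change 1.76, SE 0.56, edgeR adjusted p = 1.0). Cldn2, Clic6 and Mfrp had log2 fold changes of 1.38, 1.07 and 1.94 (SE 0.42, 0.33 and 0.62). The list had a camera adjusted p of 2.08e-29, and adjusted p = 0.197 with an estimated correlation. Its score did not separate the groups (difference 1.28, exact permutation p = 0.2). The count adjusted over the list alone was 0 without WT 3, without WT 5, without KO 2 or without KO 4, and 18 without WT 1 or without KO 6. It was 4 by DESeq2 and 0 with robust shrinkage.

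All 22 meningeal fibroblast markers were positive (median 0.24) and none passed. Their camera adjusted p was 8.79e-06, with adjusted p = 0.433 with an estimated correlation. Ptgds was at 0.33 and Col1a2 at 0.22 on the log2 scale. The call ended without WT 5 or without KO 4, and with both left out the list turned its direction (camera adjusted p = 0.905). Of 26 endothelial and mural cell markers 18 were positive (median 0.10) and none passed. The camera adjusted p was 0.00946, with adjusted p = 0.197 with an estimated correlation, and the call ended without KO 2 or without KO 6. The glucose transporter Slc2a1 was at 0.31 and Rgs5 at 0.23. Blood cell genes (8 tested, 3 positive, median -0.04, camera adjusted p = 0.383; Bpgm 0.03, Hbb-bs 0.06) were not called. Brainstem neuron and Hox genes (6 tested, 2 positive, median -0.20, camera adjusted p = 0.287; Slc18a2 -0.19, Th 0.55) were not called either.

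**Figure D2:**
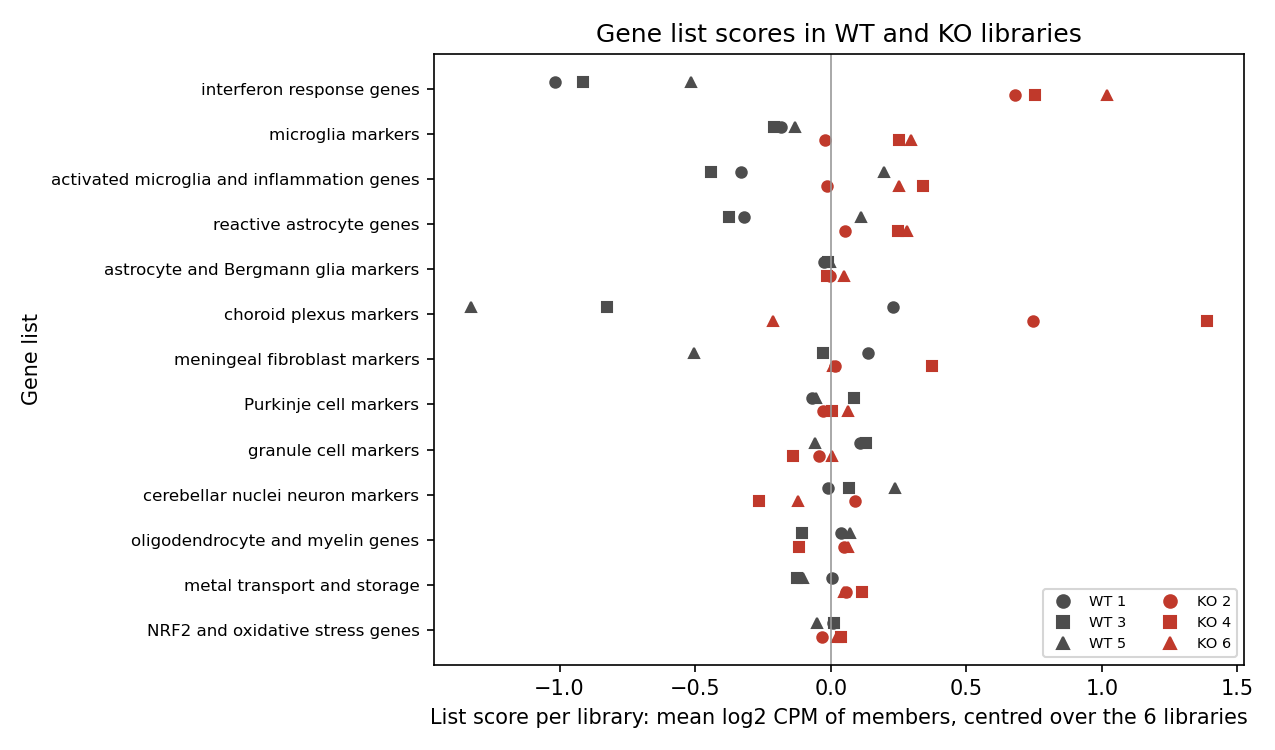
Scores of 13 gene lists per library (mean log2 CPM of the members, each centred over the 6 libraries), with WT in grey and KO in red. The interferon scores of the 3 KO libraries lie between 0.68 and 1.02 and those of the 3 WT libraries between -1.02 and -0.51, while the choroid plexus scores of the groups overlap.

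Neuronal lists showed small differences and no member passed. Purkinje cell markers were not called (34 tested, 22 positive, median 0.04, camera adjusted p = 0.333). Calb1, a calcium-binding protein of Purkinje cells, was at 863 ± 116 CPM in WT and 914 ± 150 CPM in KO (SD, n = 3 each; log2 fold change 0.08, SE 0.14). Pcp2 was at 0.19 (SE 0.14), Itpr1 at 0.10 and Atp2a2 at -0.01. Of 26 granule cell markers 25 were negative (median -0.11), with Cbln3 at -0.09 and Zic1 at -0.11. The camera adjusted p was 4.45e-06, with adjusted p = 0.273 with an estimated correlation. Of 13 cerebellar nuclei neuron markers 9 were negative (median -0.15, camera adjusted p = 0.0389, adjusted p = 0.433 with an estimated correlation), with Vamp1 at -0.16 and Dpp10 at 0.14; this call ended without WT 5, without KO 4 or without KO 6. Cerebellar interneuron markers (24 tested, 9 positive, median -0.03, camera adjusted p = 0.383; Gad1 0.04) were not called. GABA and glycine synapse genes (31 tested, 8 positive, median -0.05, camera adjusted p = 0.101; Gabra6 -0.06) were not called, nor were glutamate synapse genes (39 tested, 17 positive, median -0.02, camera adjusted p = 0.728; Slc1a2 0.05).

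Oligodendrocyte and myelin genes were not called (32 tested, 17 positive, camera adjusted p = 0.798), their median of 0.01 and mean of -0.01 differing in sign. Mbp, a structural protein of myelin, was at 0.08 (SE 0.13). Oligodendrocyte precursor markers (15 tested, 8 positive, camera adjusted p = 0.939; Tnr 0.005, Cspg5 0.06) were not called either, and there too the mean of -0.01 was opposite in sign to the median.

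Metal transporters did not pass singly. Of 41 metal transport and storage genes 28 were positive (median 0.03, mean 0.15, camera adjusted p = 0.0355, adjusted p = 0.269 with an estimated correlation), and none passed. The camera call ended without WT 3, without WT 5 or without KO 4. The manganese importer Slc39a8 was at 4.68 ± 1.33 CPM in WT and 5.33 ± 0.291 CPM in KO (log2 fold change 0.19, SE 0.24), and the manganese exporter Slc30a10 at 12.995 ± 0.943 and 15.6 ± 2.29 CPM (0.26, SE 0.15; SD, n = 3 each). The iron and manganese transporter Slc11a2 was at -0.21 (SE 0.16) and the transferrin receptor Tfrc at -0.05 (SE 0.17). The metallothioneins Mt1 and Mt2 were at 0.01 (SE 0.20) and 0.45 (SE 0.63), the ferritin gene Fth1 at -0.13 and the calcium channel gene Cacna1g at -0.04. The positive members farthest from 0, named after their values were seen, were Slc39a4 (2.14) and Slc11a1 (1.47), a metal transporter of phagocytes, and neither passed.

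Among lists of stress response and activity regulated genes 3 were lower by the preset correlation alone, and no member passed. Unfolded protein and integrated stress response genes (41 tested, 26 negative, median -0.08; camera adjusted p = 0.000409, adjusted p = 0.433 with an estimated correlation) included the chaperone Hspa5 at -0.35 (SE 0.14) and Canx at -0.07. Heat shock genes (25 tested, 21 negative, median -0.11; camera adjusted p = 0.00335, adjusted p = 0.433 with an estimated correlation) included Hspa8 at 0.07 and Hsp90ab1 at -0.18. Activity regulated early genes (31 tested, 22 negative, median -0.12; camera adjusted p = 0.0192, adjusted p = 0.481 with an estimated correlation) included Dusp5 at -0.30 (SE 0.13) and Per1 at -0.21. The early gene farthest from 0, Egr3, went the other way (1.38) and was named after its value was seen. None of the 3 was called by camera without KO 2, nor were heat shock genes without WT 5 or early genes without WT 1. In KO 6 the unfolded protein score (0.120) lay above every WT library, and the early gene score was low in KO 2 (-0.297) and between -0.017 and 0.155 in the other libraries. NRF2 and oxidative stress genes were not called (33 tested, 20 positive, median 0.01, camera adjusted p = 0.668; Sod2 0.08).

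Mitochondrially encoded genes (12 tested, 9 positive, median 0.04, camera adjusted p = 0.439; mt-Co1 0.05, mt-Cytb 0.01) were not called. Nor were nuclear respiratory chain genes (55 tested, 27 positive, mean -0.01, camera adjusted p = 0.728; Atp5b 0.04, Atp5a1 0.01). The same held for cholesterol synthesis genes (24 tested, 8 positive, median -0.06, camera adjusted p = 0.287; Srebf2 -0.13, Hmgcs1 -0.19) and circadian clock genes (20 tested, 7 positive, median -0.03, camera adjusted p = 0.702; Tef 0.02, Nr1d2 -0.04). Glucocorticoid response genes (19 tested, 11 positive, median 0.04, camera adjusted p = 0.251; Klf9 -0.08) were not called. Thyroid hormone response genes (21 tested, 9 positive, camera adjusted p = 0.798; Kcnj10 -0.20) had a median of -0.04 and a mean of 0.02, of opposite sign. Dopamine and monoamine genes (25 tested, 16 positive, median 0.03, camera adjusted p = 0.220; Ppp1r1b 0.10, Qdpr 0.20) were not called. Dystonia, parkinsonism and ataxia disease genes (51 tested, 21 positive, median -0.02, camera adjusted p = 0.728) were not called. Th, the rate-limiting enzyme of dopamine synthesis, was at 4.14 ± 1.43 CPM in WT and 6.08 ± 0.964 CPM in KO (SD, n = 3 each; log2 fold change 0.55, SE 0.28). In all, camera called 13 of 31 lists with the preset correlation, and with an estimated correlation or by fry the interferon list alone.

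Genes near Slc39a14 were counted apart, because a knockout can carry alleles of the strain it was made in around the deleted gene. None of the 8 called genes lay among the 146 tested genes within 10 Mb of Slc39a14, against 8 of 16995 elsewhere (two-sided Fisher's exact test, p = 1). With so few calls the test cannot decide whether such alleles are present. Outside the interferon list 101 tested genes had an unadjusted edgeR p under 0.01. Among them Egr3 (1.38), Esd (0.60) and 2900040C04Rik (2.57), named after their values were seen, lay in this window. They were higher in KO and did not pass. Of the 38 genes called by DESeq2, 2 lay within 20 Mb (Fisher's exact p = 0.133), Ccnb1ip1 (chromosome 14, 50789248 to 50807732) and Gm26782 (50870324 to 50880603).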

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

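The alternatives added after seeing the data were library totals implied by the FPKM values, the choroid plexus or microglia score as a covariate, a term for WT 5 and KO 4, leaving both of these out, and the position of DESeq2 calls. No paired analysis was run because the labels give no pairing and the animal numbers are shared by no KO and WT library. Without a low-count filter the 8 genes higher in KO became 117, and by DESeq2, also run without that filter, they became 35. They became 0 to 28 with single libraries left out (0 without WT 1 and without WT 3, 28 without WT 5). They became 0 with the choroid plexus score or the microglia score as covariate, 32 with the term and 37 with both libraries left out. The 0 lower genes became 25, 3 and 0 to 3 under the first 3 of these (3 without KO 4), 2 with the term and 3 with both left out. All 8 called genes were called again under RLE, upper-quartile or library-size normalization, robust shrinkage, DESeq2 and no filter, 7 with a mean CPM of at least 1 and 6 by limma-voom. Interferon genes higher adjusted over the list alone numbered 24 to 30 under all alternatives except the microglia covariate (12). With the microglia covariate the list median was 1.40, against 1.47 in the main fit, and 28 of 29 members were positive. The list count fell from 13 to 1 by fry and to 1 with an estimated correlation, and the meningeal list reversed with WT 5 and KO 4 left out (adjusted p = 0.905). DESeq2 calls within 20 Mb of Slc39a14 numbered 2, and 38 DESeq2 calls were shared with the authors. The cause of these changes was not tested, except that covariates and left-out libraries reduce the degrees of freedom. Among values of single named genes and lists, 1900 stayed the same, 70 became stronger, 97 became weaker and 1 reversed. For genes and lists this means that a call was kept, gained or lost. The count of choroid plexus markers higher adjusted over the list alone is included and was judged by the size of its change. The fold change of Slc39a14 did not pass anywhere and took both signs (-0.12 to 0.09). The median of all genes moved by less than 0.1 under each scaling (-0.02 to 0.01), more than the medians of several uncalled lists. In the simulation, 42% of 1.5-fold changes were recovered with 3 libraries per group, a share that may be too high for the real libraries.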

Other observations

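Apart from leaving out single libraries, the tests in this part were chosen after the results were seen. Beyond the fixed lists, the authors' deposited table also called Parp9, Parp12 and Gbp6, known interferon-inducible genes, higher in KO (log2 fold changes of 1.18, 0.79 and 1.60), with the complement gene C4b (1.31) and the matrix genes Ltbp4 (0.59) and Col9a3 (0.63). The processed pseudogene Gm3375 was called higher there with a smaller adjusted p than these (log2 fold change 3.29, authors' adjusted p = 3.10e-12). It did not pass in the edgeR fit (edgeR adjusted p = 0.0532). In the edgeR fit C4b was at 15.7, 19.1 and 19.4 CPM in WT 1, 3 and 5 and 30.6, 41.1 and 62.7 CPM in KO 2, 4 and 6, and did not pass (adjusted p = 0.176). Cd74, of antigen presentation, and the interferon-inducible GTPase Gbp4 were highest in a single WT library: Cd74 was at 2.90, 3.76 and 18.2 CPM in WT 1, 3 and 5, and Gbp4 at 2.18, 1.34 and 18.2 CPM. Their KO values (Cd74 2.45, 9.57 and 10.4 CPM; Gbp4 3.71, 6.77 and 5.39 CPM) lay below WT 5. WT 5 was also above every KO library for Igtp and Irgm2, which overlap in the annotation, and for H2-Q6 and H2-Q7, which are close copies. It was not for B2m (94.5, 119 and 121 CPM in KO 2, 4 and 6; 89.3 CPM in WT 5), H2-K1 (56.0, 57.7 and 101 CPM; 63.5 CPM in WT 5) or Gbp7 (5.60, 12.9 and 6.68 CPM; 11.7 CPM in WT 5). The interferon score of WT 5 was -0.51, nearer to the KO libraries than those of WT 1 (-1.02) and WT 3 (-0.92). These genes were chosen after their values were seen.

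Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many called genes as the real split (8, the highest other 2), 1 as many interferon genes in one direction (27, the highest other 0) and 1 as many lists (13, the highest other 10), the real split itself each time. With 10 splits the share is never under 0.1, which is too few to decide. In each of the other splits camera called 5 to 10 lists with the preset correlation. Such calls thus also arose between groups that mix the genotypes.

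The interferon score was higher in each KO than in each WT library, as were 23 of the 29 tested members singly. Of all tested genes 7.26% had groups that did not overlap, in either direction. A larger share of microglia as the whole cause is argued against by the interferon score less the microglia score, which was higher in KO by 1.28226 (pooled SD 0.186; exact permutation p = 0.1, the smallest possible), carry-over of choroid plexus by the list median of 1.73449 with that score as covariate, and a single library by the lowest median of 1.3355 with 1 library left out. With either score as covariate no gene was called: Oasl2 went from 2.96 (SE 0.27) to 3.34 (SE 0.31, adjusted p = 0.0547) with the choroid plexus score, where fold and standard error both grew, and with the microglia score to 2.46 (SE 0.43, adjusted p = 0.823), Ifit1 from 2.60 (SE 0.27) to 1.58 (SE 0.35), and list members called alone from 27 to 12 (25 with the choroid plexus score). With the microglia score, the folds of Oasl2, Ifit1 and Ifi27 (1.60 to 1.40) fell and their standard errors grew, and that score was higher in each KO than in each WT library. The list median was 1.40 with the microglia score and 1.47 without a covariate, with 28 and 29 of the 29 members positive. A change of state within microglia or other cells stays open, as untested. The genotype may raise these genes, which is a hypothesis found and examined on the same 6 libraries, whose labels the Slc39a14 count did not check.

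The choroid plexus markers were higher in KO on average. Different amounts of choroid plexus taken along in dissection are consistent with the values: the score ranged over 1.55756 among WT libraries alone, more than the difference of 1.28 between KO and WT, and 14 of 18 markers followed Ttr within groups with a correlation above 0.9, as 1.28% of all tested genes did. Of the 20 listed markers 0 stand in another list, though Enpp2 is also known from oligodendrocytes. That genotype raises these transcripts cannot be told apart from this (exact permutation p = 0.2, with 3 against 3 libraries unable to go below 0.1).

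Genes changed side by side on chromosome 7: of 26 tested genes that start between 16 and 17 Mb, 5 had an unadjusted p under 0.01: Gm29443, 9330104G04Rik, Pnmal1 and Gm42372 lower (-2.03, -1.90, -0.47 and -0.80) and Dhx34 higher (0.44), none passing in the edgeR fit, while DESeq2 and the authors' deposited table called Gm42372. In 0 of 1000 shuffles did as many such genes fall in any 1 Mb (shuffled mean 2.35), which argues against chance placement of genes that vary independently. The shuffles moved each gene on its own, so they cannot exclude neighbours that vary together between libraries. Of the 5 genes 0 pairs overlap, which argues against reads shared among these 5 gene models only. Reads shared with other genes were not tested, and Gm29443 is annotated as antisense. Alleles of another strain at this locus may account for the pattern and cannot be told apart from an effect of the knockout. KO and WT libraries did not overlap for 5 of the 5 genes, which were picked for their difference. Genes low in some libraries of both genotypes and several-fold higher in others had been taken first as the third pattern, and this one replaced it after both results were seen.

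Those switching genes numbered 9, against a mean of 0.06 and at most 1 in 100 simulated tables. Simulated genes had the dispersion of the trend for their level, so genes varying above that trend exceed this reference by its setting. There were 0 pairs of neighbours within 2 Mb sharing a pattern, but genes on different chromosomes shared one. Gm8210, Pttg1, Gm11868 and an unannotated locus on chromosome 7 were low in WT 1 and KO 2 only. Gm8730 and Rpl29 were high in WT 1 and KO 2 only. Rpl29 was at 55.2 and 48.9 CPM in WT 1 and KO 2 and between 0.628 and 1.79 CPM in the other 4 libraries. Apart from the switching genes, Ccnb1ip1 had 30, 20 and 18 counts in KO and 0 in all WT libraries, at least 22.4-fold higher against a floor of 3 counts over the WT group. It did not pass in the edgeR fit (edgeR adjusted p = 0.0621) and lay within 20 Mb of Slc39a14, as given above.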
